A study of Mus musculus with 12 samples.

How the data were processed

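Sorted keratinocytes of 12 mouse samples were measured on Affymetrix MTA-1_0 arrays, 3 in each of 4 groups. Groups were taken from the sample titles, and replicates are named by the code printed there. The authors deposited log2 signals per transcript cluster, made with Affymetrix Expression Console and RMA per the submitters' processing notes. RMA corrects the background, normalizes quantiles and summarizes probes, so it makes the distributions of arrays alike and can hide a shift shared by most genes. The values carry 2 decimals and annotation of NetAffx build 34 on mm10, per the file headers. The authors' deposited table also holds signed fold changes of mean unlogged signals, negative where the first group is lower, and a p-value and a q-value for each comparison, per the file headers. Its p-values were recomputed as an equal-variance test on unlogged signals, with the same count under 0.05 in the suprabasal genotype comparison (4499). How its q-values were made is not given in the sources used here, and some lie below their own p. Its counts of clusters with q under 0.05 were 0 in all comparisons, and 86 clusters had q under 0.10 between wild-type layers.

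Of 72688 probe sets, 6732 (9.26%) were controls or normalization sets and were left out, which left 65956 clusters with no filter on dim ones. The platform annotation gave 1 symbol to 30638 clusters and several to 2176, which were left unnamed in the text; 669 were named from the symbol in the deposited file and 32473 had none. Where a gene had several clusters, the one with the highest mean over 12 arrays stood for it, which gave 30807 genes.

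All comparisons came from 1 limma fit of 4 group means to the 12 arrays, with empirical Bayes moderation and Benjamini-Hochberg adjustment over all clusters, called at adjusted p under 0.05. The 4 pairwise comparisons were those that the series design names, and the interaction was fitted as well. The design names an unpaired 2-sided Student test with a false discovery rate; it was run as an alternative, because the moderated test borrows spread across clusters. In the first version of that alternative, a cluster whose values were identical within both groups, Spock2, was called falsely through a division by 0; it was then treated as untestable, leaving 65955 in that comparison.

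Gene lists were tested with limma's camera at a preset correlation of 0.01 on 24 lists, adjusted within each comparison, and again with an estimated correlation and with fry. Across comparisons camera called 43 of 120 tests, and 0 of these held with an estimated correlation. The lists cover epidermal layers, hair follicle, Wnt, Notch, nuclear envelope, spindle orientation, cell cycle, p53, stress, interferon, lipid synthesis, immediate-early genes and 8 other cell types. Annotated terms of 10 to 500 genes were tested against 19579 annotated genes, an enrichment added after seeing the data. Genes were named by rule: up to 10 called genes each way by size whose groups did not overlap, without predicted, microRNA, small nucleolar, olfactory, vomeronasal and ribosomal models; the 5 smallest p each way as values where none was called; up to 4 called members per list; 5 called each way for the interaction; and 18 genes in every comparison. Of those 18, 17 were measured alone; Emd shares its cluster with other symbols and is not reported. Some genes that the rules select are not reported here. Lists, naming rules, tests and the alternatives not described as added were chosen before the data were examined.

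The codes pair the samples, which comes from the data and not from the labels. Deviations from group means of arrays with the same code correlated at 0.269, 0.533 and 0.37 in wild type and 0.136 and 0.241 in bitransgenic cells, against a median of -0.066 for different codes. The first number of the code paired the genotypes in suprabasal arrays, where its 3 pairs correlated at 0.485, 0.308 and 0.333, but not in basal arrays, where its 2 pairs correlated at 0.229 and -0.157. This too comes from the data and not from the labels.

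The alternatives were centring each array, cyclic loess, clusters above the median of cluster means, clusters with 1 symbol, moderation with trend and robust settings, array weights, code blocks, only the 2 groups compared, the design's test and each array left out. Added after seeing the data were the test on unlogged signals, a term for sex, leaving out chromosomes X and Y, camera with a term for sex or other scaling, camera with the first number of the code as a block, other scaling with each array left out, bounds against the 95th percentile of intronic controls of each array, and a block of the 3 suprabasal pairs. Simulated data had 200 changed clusters of 65956, 50 each with log2 changes of 0.5, 1, 2 and 4. On these the basal genotype comparison recovered 44% of log2 changes of 0.5 and 88% of changes of 1, with 9 false calls. R 4.3.3, limma 3.58.1, the data.table package (1.17.8), Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 were used.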

Results

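RNA was measured in keratinocytes sorted from the skin of mice of the FVB/N strain on postnatal day 4. Keratinocytes are the epithelial cells of the epidermis: dividing cells sit in its basal layer, and cells that leave it stop dividing and build the barrier in the suprabasal layers. The 12 arrays fell into 4 groups of 3: wild-type basal, bitransgenic basal, wild-type suprabasal and bitransgenic suprabasal. The series title names progerin, the truncated form of lamin A that causes Hutchinson-Gilford progeria, together with Wnt signalling, the symmetry of cell division and proteins of the nuclear envelope. Each array gave a log2 signal for 65956 transcript clusters, with array medians between 5.28 and 5.46. Intronic control probe sets, which stand for background, had medians of 4.86 to 5.32 on the arrays, and between 7.1% and 12.3% of clusters lay above the 95th percentile of these controls. A cluster at or below that mark on all 3 arrays of a group is called not above background there, a rule set after the result was seen. Its log2 differences are printed as measured and its folds as bounds against the mark, with no fold where both groups were not above background. The number of arrays limits the precision of every comparison. The labels give each array a code but do not say that the codes are separate animals, so the p-values measure only the spread between these samples.

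Lmna, the mouse gene for lamins A and C, is the gene behind progerin and was read first. Its cluster TC0300002313.mm.1 lies on chromosome 3 from 88481148 to 88509956 (mm10, minus strand). The signal of Lmna was 10.91 ± 0.14 in wild-type basal and 10.87 ± 0.14 in bitransgenic basal arrays, and 10.71 ± 0.15 and 10.80 ± 0.02 in the suprabasal arrays (log2, mean ± SD, n = 3 each). The bitransgenic minus wild-type difference was -0.03 ± 0.098 (SE) in basal cells, with limma's adjusted p = 0.908, and 0.09 ± 0.098 in suprabasal cells, with limma's adjusted p = 0.90. The authors' deposited table gave signed folds for Lmna of -1.023 in basal and 1.058 in suprabasal cells. The probes were designed on the mouse transcript, and the labels do not describe the transgenes, so these values do not check the genotype labels.

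Genes on the sex chromosomes differed between arrays of the bitransgenic groups. Xist, the RNA that silences an X chromosome in female cells, was between 4.09 and 4.28 on all 6 wild-type arrays, while the Y-linked helicase gene Ddx3y was between 8.0 and 8.60. The bitransgenic arrays X721_05_H and X721_05_L, where H marks basal and L suprabasal samples in the titles, had the same pattern, with Xist at 4.23 and 4.20. The other 2 bitransgenic arrays of each layer had Xist between 10.69 and 11.08 and Ddx3y between 4.56 and 5.04. Genotype comparisons in both layers therefore set arrays of 1 sex pattern against groups holding 2 arrays of the other.

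**Figure D1:**
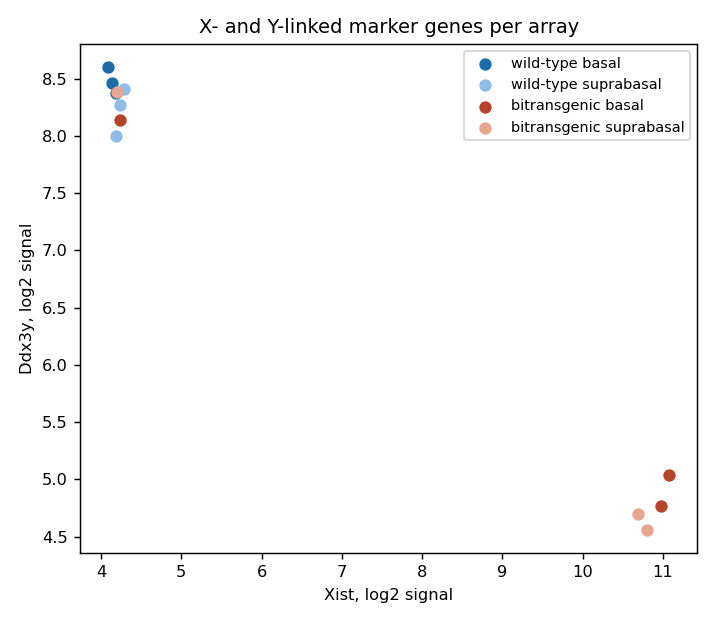
Log2 signal of the X-linked gene Xist (horizontal axis) against the Y-linked gene Ddx3y (vertical axis), 1 point per array, coloured by group. All 6 wild-type arrays have Xist below 4.3, and 2 of 3 bitransgenic arrays in each layer have it above 10.6.

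The comparison of basal with suprabasal cells in wild-type skin asks what separates the layers without the transgenes. Genes of mitosis were higher in basal cells. Mki67, the proliferation marker, rose by 1.19 ± 0.195 (log2, SE) with limma's adjusted p = 0.0362 (chromosome 7, 135689788 to 135716379). Hmmr, a protein of the mitotic spindle, was called too (limma's adjusted p = 0.0395), with 8.31 ± 0.19 in basal and 6.51 ± 0.52 in suprabasal arrays (SD, n = 3). It was not above background in suprabasal arrays and its bound was under 1, so no fold is given. Pigment-cell genes moved furthest in the other direction. Dct, a melanin-synthesis enzyme, was 6.71 ± 0.51 in basal arrays, not above background, and 12.20 ± 0.57 in suprabasal arrays. It was at least 13.3-fold lower in basal cells with limma's adjusted p = 0.0348 (chromosome 14, 118012790 to 118052246).

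The 10 called genes with the largest measured increases towards basal cells were mostly genes of cell division. None of the 10 was above background in suprabasal arrays, so their order is not read. Higher in basal cells were Anln, the actin-binding protein of the cleavage furrow (at least 2.0-fold), Ccnb1, cyclin B1 (at least 2.0-fold), Cdk1, the mitotic kinase (at least 1.9-fold), Prc1, which bundles microtubules of the central spindle (at least 1.4-fold), and Nusap1, a spindle protein (at least 1.1-fold). Called with no fold were Hmmr, Prr11, Shcbp1, a midbody protein, Aspm, a spindle-pole protein, and Cenpe, a kinetochore motor, and the last 3 were not above background in basal arrays either. Of the 30 measured genes of the cell cycle list, 8 rose over all genes and 28 adjusted over the list alone, with a median difference of 1.12, or 0.765 with genes at their bounds and those not above background in either group at 0. Ccnb2 rose by 1.11, and Cenpf was called but not above background in suprabasal arrays. The list was called by camera (adjusted p = 4.54e-20), but adjusted p = 0.394 with an estimated correlation. Among annotated terms, cell division held 43 of the genes that rose where 2.74 were expected by chance (Fisher's exact test, one-sided, adjusted p = 4.49e-36), and 18 of 1718 terms were enriched. Fisher's test treats genes as independent, though the estimated correlation within the cell cycle list was 0.853. Its background also held dim genes, so these p-values can be too small.

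Among the 10 called genes with the largest measured decreases, only Krt79, a keratin of the upper hair follicle (-2.25), was above background in both groups. Besides Dct, lower by bounds that background sets were Pmel, the fibril protein of melanosomes (at least 12.5-fold), the melanin-synthesis enzymes Tyrp1 (at least 6.6-fold) and Tyr (at least 2.8-fold), and Mlana, a melanosome protein (at least 5.5-fold). The others were Vim, the intermediate filament of mesenchymal cells (at least 3.6-fold), the ion channel gene Mcoln3 (at least 2.9-fold), the amino acid transporter gene Slc7a8 (at least 2.6-fold) and Ccer2 (at least 2.4-fold). Of 8 melanocyte genes, 5 fell over all genes and 8 adjusted over the list alone, with a measured median of -4.92, or -1.98 at the bounds. The melanocyte list had camera adjusted p = 2.12e-06, and adjusted p = 0.394 with an estimated correlation. Melanin biosynthesis was 1 of 2 annotated terms enriched among genes that fell, with 4 of its 10 genes (Fisher's exact test, one-sided, adjusted p = 0.00868), and the other was phospholipid metabolism (5 of 32 genes, adjusted p = 0.0418). The same limits of Fisher's test hold for these 2 terms.

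Genes of the epidermal barrier and of sterol synthesis were lower in basal cells. Klk7, a protease that releases surface cells, was 10.21 in suprabasal and 7.99 in basal arrays, a mean under the background mark of each basal array. As measured it fell by 2.22, and Sprr1a, a protein of the cornified envelope, was at least 1.5-fold lower. These were 2 of the 28 measured barrier genes over all genes, against 11 adjusted over the list alone, with a median of -0.45 (camera adjusted p = 0.00116, and adjusted p = 0.496 with an estimated correlation); 13 of the 28 were not above background in either group, and at the bounds the median was 0. Over the 10 barrier genes above background in both groups the median was -0.88. Lss, an enzyme of cholesterol synthesis, was called lower but not above background in either group. Of the 17 lipid synthesis genes 2 fell over all genes and 5 adjusted over the list alone (median -0.37, camera adjusted p = 0.00197, and adjusted p = 0.407 with an estimated correlation). Of the layer markers, the basal keratins Krt5 (0.34) and Krt14 (0.27), the basal integrin Itga6 (0.87), Trp63 (0.43), the suprabasal keratins Krt1 (-0.06) and Krt10 (-0.17), and Flg, the filaggrin gene (-0.82), were not called. Krt5 and Krt14 lay within 0.33 of the highest signal of each wild-type basal array, so their differences may be compressed. The basal keratinocyte list of 17 genes had a median of 0.43, with 0 called over all genes and 1 adjusted over the list alone (camera adjusted p = 1.36e-05, and adjusted p = 0.407 with an estimated correlation).

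Of the groups that the series title points to, the nuclear envelope and spindle orientation lists were called between wild-type layers and both Wnt lists were not. The 26 nuclear envelope genes had a median of 0.20 and 0 calls over all genes, while adjusted over the list alone 6 rose, among them Lmnb1, Tmpo, Nup153 and Lbr, and Syne4 fell (camera adjusted p = 0.000199, and adjusted p = 0.224 with an estimated correlation). Gpsm2, which ties the spindle to the cell cortex, rose by 0.80 as the only one of 25 spindle orientation genes called over all genes, against 1 higher and 1 lower adjusted over the list alone (median 0.06, camera adjusted p = 0.0186, and adjusted p = 0.41 with an estimated correlation). In neither group above background were 11 of the 26 and 7 of the 25 genes, and at the bounds both medians were 0. Over the 11 nuclear envelope and 17 spindle orientation genes above it in both groups, the medians were 0.307 and 0.133. Wnt10a, a Wnt ligand, was called higher but not above background in suprabasal arrays, and the list of 41 Wnt pathway components was not called (median 0.02, adjusted p = 0.235). Cxcl14, a chemokine, rose by 0.81. Immediate-early genes had a median of 0.24 with 0 of 14 called over all genes or adjusted over the list alone (camera adjusted p = 0.0485, and adjusted p = 0.568 with an estimated correlation). This median was -0.02 without X667_06_H, 0.10 without X721_08_H, 0.03 without X682_11_L, 0.69 without X682_11_H and 0.53 without X667_06_L, and the call was lost without any of 7 arrays (adjusted p = 0.0516 to 0.454). The spindle orientation list was not called without X721_08_H (adjusted p = 0.0977, median 0.04) or X682_11_L (0.091, median 0.035), and its median was 0.12 without X721_08_L and 0.095 without X682_11_H.

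Lists of other cell types were called lower in wild-type basal cells, but on signals mostly under the background mark. None of the Merkel, muscle, adipocyte, immune and endothelial genes was above background in either group, nor were 18 of the 19 hair shaft genes. Their medians are measured values and do not show these cell types. Of the Merkel cell markers, Atoh1 was called lower as 1 of 6 over all genes and 6 adjusted over the list alone (median -0.34, camera adjusted p = 0.000478). Ckm was called among 8 muscle genes, with 4 adjusted over the list alone (median -0.16, adjusted p = 0.0141), and Plin1 among 6 adipocyte genes, with 1 adjusted over the list alone (median -0.12, adjusted p = 0.049). The 12 immune genes (median -0.17, adjusted p = 0.00367), the 8 endothelial genes (median -0.12, adjusted p = 0.0225) and the 19 genes of the hair shaft and its sheath (median -0.16, adjusted p = 0.033) had 0 calls over all genes and 2 each adjusted over the list alone. None of these 6 calls held with an estimated correlation: adjusted p = 0.394 for Merkel and endothelial genes, 0.407 for muscle, adipocyte and immune genes, and 0.528 for hair shaft genes with an estimated correlation. The lists not called were early differentiation (adjusted p = 0.0865), hair follicle epithelium (0.602), Wnt targets (0.232), Notch (0.855), p53 and senescence (0.154), keratinocyte stress (0.0658), interferon response (0.898), fibroblast (0.248) and erythroid genes (0.293). Of the 14 lists called, 11 were still called with arrays centred and 7 with cyclic loess: both scalings lost immediate-early (adjusted p = 0.309 and 0.429), adipocyte (0.146 and 0.429) and endothelial genes (0.13 and 0.562), and loess also hair shaft (0.192), spindle orientation (0.73), immune (0.0968) and muscle genes (0.0717). Both added early differentiation genes downwards (adjusted p = 0.00845 and 9.69e-05), and loess added Wnt targets downwards (0.0455). The first was lost without any of 2 arrays when centred and never with loess, the second without any of 5. Without 1 array, the adipocyte call was lost for 9 arrays (adjusted p = 0.0516 to 0.0897), the hair shaft call without X682_11_H (0.199) or X682_11_L (0.0532) and the endothelial call without X682_11_H (0.073), while the barrier median was -0.79 without X682_11_H. For Notch the median was -0.14 and the mean 0.04, with the test upwards, and for interferon genes the median was -0.07 and the mean 0.01, with the test downwards.

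In all, limma called 957 clusters between wild-type layers, 268 higher and 689 lower in basal cells, standing for 547 named genes, and 103 of them differed at least 2-fold as measured, 27 at the bounds. Of the 957, 742 were not above background in either group (164 higher, 578 lower), 111 were not above it in the dimmer group only, and 104 were above it in both on 1 array or more. All 957 had groups that did not overlap, as did 27.5% of all clusters where chance gives 10%. The split between directions depended on scaling: centring each array on its median gave 342 calls, 227 higher and 115 lower, and cyclic loess 262, 130 higher and 132 lower. In wild type the array level went with the layer. Cluster medians were 5.28 to 5.36 on basal and 5.39 to 5.46 on suprabasal arrays, with a median difference of -0.047 over all clusters. How many of the 578 lower calls not above background reflect this shift was not tested. The codes pair basal with suprabasal arrays, and with the code as a random block the count was 3600, with Lor (-0.56, limma's adjusted p = 0.0389) and Lmnb1 (0.74, limma's adjusted p = 0.0374) added and the adipocyte list lost (adjusted p = 0.0567). With pairs as a fixed block the calls were 616 higher and 696 lower, of which 351 were among the 957, and Ckm (0.0923), Plin1 (0.117) and Atoh1 (0.0623) were no longer called. The count was 0 without wild-type X721_08_H, X682_11_L or X721_08_L, or bitransgenic X721_05_H, and 9 (5 higher and 4 lower) without bitransgenic X682_05_L, 30 (20 higher and 10 lower) without wild-type X682_11_H, 131 without bitransgenic X722_07_H, 545 without wild-type X667_06_L, 602 without bitransgenic X667_05_H and 2903 without bitransgenic X721_05_L.

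**Figure D2:**
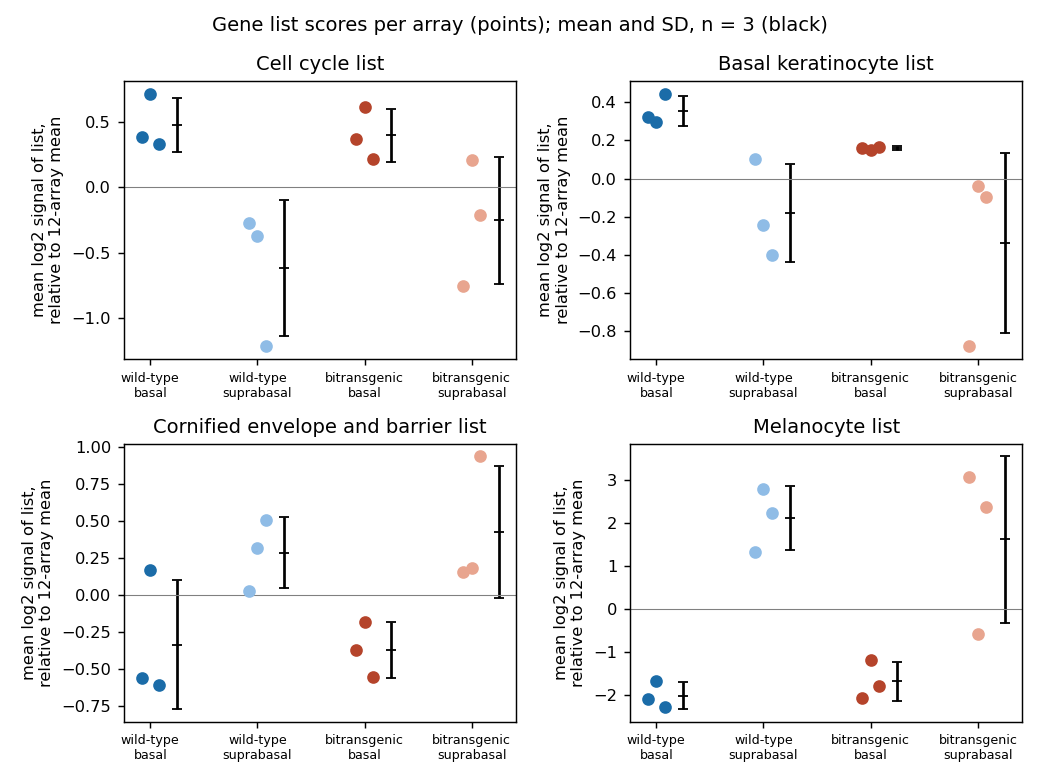
Mean log2 signal of the genes of each list per array, relative to the mean over 12 arrays (vertical axes), for the 4 groups (horizontal axes); points are arrays and black marks the mean and SD of 3. The suprabasal bitransgenic array X667_05_L has a melanocyte score of -0.585, against 3.059 and 2.354 for the other arrays of its group.

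The same layers in bitransgenic skin gave values in the same direction for most of these genes, but no cluster passed the test. Dct was 7.17 in basal and 11.47 in suprabasal arrays and Tyrp1 6.45 and 10.89, with basal arrays not above background (differences of at least 9.1-fold and 6.1-fold), and Pmel, above background on only 1 basal array, was 7.40 and 11.46. The melanocyte list had a measured median of -3.87, or -1.56 at the bounds, with 0 of 8 genes called over all genes and 8 adjusted over the list alone (camera adjusted p = 4.71e-14, and adjusted p = 0.194 with an estimated correlation). The suprabasal array X667_05_L stood apart: its Dct signal was 9.14, against 12.98 and 12.29 on the other arrays of the group, and it correlated with its basal partner at r = 0.9964 across clusters, which are not independent replicates. X721_05_L stood apart in basal genes, with Krt5 at 12.20 against 13.32 and 13.19, Itga6 at 8.18 against 9.93 and 9.83, and a basal keratinocyte score of -0.878 against -0.038 and -0.096 on the other arrays of the group.

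Barrier genes were lower in basal than in suprabasal bitransgenic cells, with a measured median of -0.86 over 28 genes; 10 were not above background in basal arrays and 8 in neither group, which gave 0 at the bounds. None was called over all genes and 6 were called adjusted over the list alone, among them Klk7 (-2.11), Flg (-1.51), Casp14 (-0.95) and Sprr1a (at least 1.4-fold), and camera gave adjusted p = 8.27e-16, and adjusted p = 0.194 with an estimated correlation. Over the 10 barrier genes above background in both groups the median was -0.82. Of the early differentiation genes, Dmkn (-0.73), Sbsn (-0.57) and Dsc1 (-1.09) were called adjusted over the list alone and 0 over all genes (median -0.16, camera adjusted p = 0.0237, and adjusted p = 0.655 with an estimated correlation). Cholesterol and lipid synthesis genes had a median of -0.30, with 0 called over all genes and 5 adjusted over the list alone, including Insig1 (-0.82) and Lss, which was not above background (camera adjusted p = 1.6e-09, and adjusted p = 0.194 with an estimated correlation). Cell cycle genes had a median of 0.69 and basal keratinocyte genes one of 0.55, with 0 calls over all genes and 0 adjusted over the list alone in either (camera adjusted p = 4.71e-14 and 1.58e-05, and adjusted p = 0.60 for both with an estimated correlation). Wnt targets had a median of -0.11 and 0 calls on either basis (camera adjusted p = 0.0237, and adjusted p = 0.631 with an estimated correlation). With cyclic loess the calls of early differentiation (adjusted p = 0.0515) and Wnt targets (0.0709) were lost, and centring added Merkel cell genes downwards (0.0498). The Merkel call was lost without any of 6 arrays. The early differentiation call was also lost without X722_07_H (adjusted p = 0.158, median -0.09) or X667_05_L (0.165), and that of Wnt targets without X722_07_H (0.102), X721_05_L (0.0616) or X682_05_L (0.225), with medians of -0.17 without X721_05_H and -0.18 without X667_05_L. The median of basal keratinocyte genes was 0.19 without X721_05_L, and that of barrier genes -0.43 without X682_05_L.

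By limma 0 of 65956 clusters were called between bitransgenic layers, with 4916 at an unadjusted p under 0.05 where chance gives 3298, and a lowest adjusted p of 0.605. The unmoderated test that the series design names called 0 on log2 values (3954 at an unadjusted p under 0.05) and 0 on unlogged signals (3898). The genes with the smallest p, given as values only, were Fanca (0.43), Cdc25b (0.58), Ube2s (0.49), Stk33 (0.52) and Troap (0.43), and Snx13 (-0.52), Sema4g (-0.49), Alcam (-1.12), Cd200 (-1.42) and Fndc9 (-1.12). Of these 10, 7 were not above background in either group. Of the 957 clusters called in wild type, 755 (78.9%) had the same sign in bitransgenic cells, where 57.2% of all clusters did. The share was 92.2% of the 268 higher and 73.7% of the 689 lower in wild type. Sizes were smaller: the 268 had medians of 0.652 in wild type and 0.295 in bitransgenic cells, the 689 of -0.44 and -0.077. Choosing clusters on wild-type values enlarges their wild-type differences, so these medians do not measure a genotype effect. Adjusted over those 957 alone, 142 were called in bitransgenic cells, 139 of them in the same direction. The 142 is not independent support. Both comparisons share 1 estimate of spread per cluster, so choosing clusters called in wild type favours small spread and lowers their p in bitransgenic cells. The difference between the layer effects is the interaction, which called 0 clusters. Without the suprabasal array X667_05_L the bitransgenic count was 126, 10 higher and 116 lower, and without the basal array X667_05_H it was 1, Psapl1 (-2.10), named after its value was seen.

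**Figure D3:**
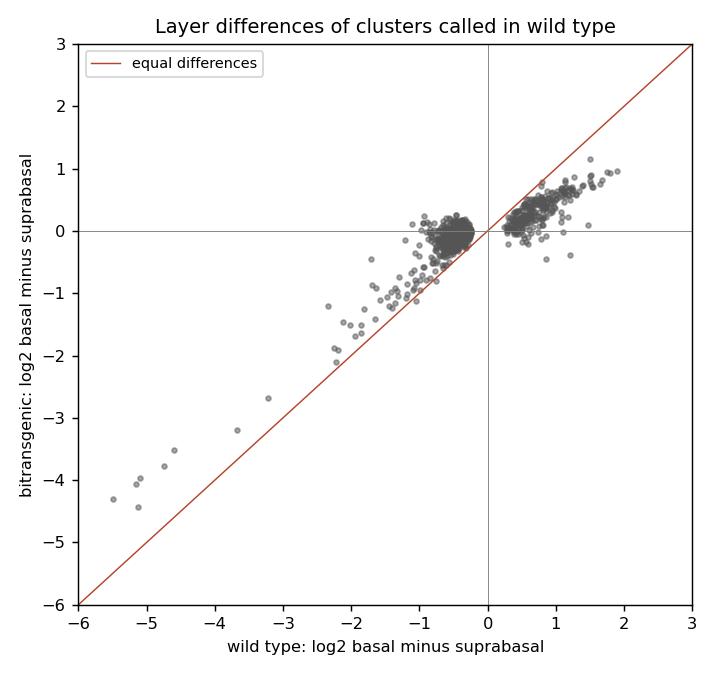
Basal minus suprabasal log2 difference in wild type (horizontal axis) and in bitransgenic cells (vertical axis), 1 point for each of the 957 clusters called in wild type; the line marks equal differences. The clusters were chosen on the horizontal axis, and 755 of them have the same sign on the vertical axis.

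The comparison of genotypes in basal cells asks what the transgenes change where stem and dividing cells lie. No single gene passed the test. By median, the largest shift of a list was in the immediate-early genes, which tissue dissociation also induces: 13 of 14 were below 0, with a median of -0.57, Fos at -0.84, Egr1 at -0.59 and Hspa1a at -1.11. The list had 0 calls over all genes and 0 adjusted over the list alone, and camera gave adjusted p = 2.24e-05, and adjusted p = 0.508 with an estimated correlation. Wild-type basal arrays differed among themselves in these genes, with list scores of 0.882 for X667_06_H, 0.707 for X721_08_H and -0.365 for X682_11_H. The median was -0.37 without X667_06_H, -0.35 without X721_08_H and -0.99 without X682_11_H, and the list was called each time. By mean, stress genes moved as far the other way, at 0.557 against -0.549 for immediate-early genes (stress median 0.27, not called, adjusted p = 0.0916).

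Wnt pathway components had a median of -0.08 in bitransgenic against wild-type basal cells, with 18 of 41 above 0 and 23 below, Fzd8, a Wnt receptor, at -0.51, Wnt10a at -0.42 and Wls, which carries Wnt ligands to the surface, at -0.49. Spindle orientation genes had a median of -0.09 and 18 of 25 below 0, with Gpsm2 at -0.53 and its partner Numa1 at -0.22, and the nuclear envelope genes -0.09 and 19 of 26 below 0, with Sun1, which links lamins to the cytoskeleton, at -0.44 ± 0.131 (SE, limma's adjusted p = 0.247) and Zmpste24, the protease that matures lamin A, at -0.35. Basal keratinocyte genes had a median of -0.18, with 14 of 17 below 0, and cell cycle genes one of -0.09, with 23 of 30 below 0. In these 5 lists 0 genes were called over all genes and 0 adjusted over the list alone. Camera gave adjusted p = 0.000509 for Wnt components and for spindle orientation, 0.0102 for nuclear envelope and basal keratinocyte genes, and 0.0213 for cell cycle genes, against adjusted p = 0.27, 0.481, 0.463, 0.638 and 0.95, in that order, with an estimated correlation. Of the Wnt components 24 of 41 were not above background in either group, of the nuclear envelope genes 10 of 26 and of the Notch genes below 14 of 20. With these at 0 and others at their bounds the medians were 0 for Wnt, nuclear envelope and Notch genes, -0.06 for spindle orientation, -0.15 for basal keratinocyte and -0.09 for cell cycle genes. Where most of a list is set to 0, its median is 0 whatever the other genes show. Over the genes above background in both groups the medians were -0.14 for 15 Wnt, -0.10 for 15 nuclear envelope and -0.17 for 5 Notch genes. Notch genes had a median of -0.09 with Dtx4 (-0.37) called adjusted over the list alone and 0 over all genes (camera adjusted p = 0.045, and adjusted p = 0.481 with an estimated correlation). Muscle genes, none above background, had a median of 0.145 with 0 calls on either basis (camera adjusted p = 0.00584, and adjusted p = 0.481 with an estimated correlation). Of the 8 lists called, 5 were still called with arrays centred and 4 with cyclic loess: both scalings lost the basal keratinocyte (adjusted p = 0.092 and 0.206), cell cycle (0.301 and 0.343) and Notch lists (0.114 and 0.208), loess also lost nuclear envelope genes (0.206), and stress genes were added upwards (0.0107 and 0.0334). The added call was lost without any of 2 arrays when centred and of 4 with loess. The cell cycle median was 0.01 without X722_07_H (adjusted p = 0.313) and 0.05 without X682_11_H (0.50), so its direction depended on these arrays, and it was -0.22 without X667_05_H, -0.15 without X667_06_H and -0.15 without X721_08_H. The nuclear envelope call was lost without X682_11_H (adjusted p = 0.165, median -0.01) or X722_07_H (0.088, median -0.02), and its median was -0.06 without X721_05_H. The basal keratinocyte call was lost without X682_11_H (adjusted p = 0.051), and the Notch call without X667_06_H (0.0835), X721_08_H (0.147), X667_05_H (0.148) or X722_07_H (0.088). Without X721_05_H the medians of Wnt components and spindle orientation genes were -0.13 and -0.145, and the latter was -0.05 without X667_05_H and -0.03 without X721_08_H.

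Wnt targets were not called in basal cells (camera adjusted p = 0.114): their median was 0.02 and their mean -0.12, with the test downwards, Lef1 at -0.79 ± 0.397 and Axin2 at -0.19 ± 0.139 (SE). Cxcl14 (-0.89) and Tnfrsf19 (-0.66) among hair follicle genes and Cxcl2 (0.40) among stress genes were called adjusted over the list alone and not over all genes. Of the interferon genes 1 was called each way adjusted over the list alone. Lmnb1 (-0.25), Lmnb2 (0.02), Sun2 (0.02), Krt5 (-0.07), Krt14 (-0.03), Itga6 (-0.15), Trp63 (-0.11), Krt1 (-0.22), Krt10 (-0.13), Lor (0.09), Flg (-0.64), Mki67 (-0.38) and Cdkn1a (0.07) were not called either. The genes with the smallest p, given as values only, were Pldi (0.51), Cxcl2, Ifna4 (0.44), Svs3b (0.43) and Sh3bgr (0.41), and Mplkip (-0.58), Elmod2 (-0.46), Cog6 (-0.65), the histone gene H3c3 (-1.30) and Cxcl14. Of these 10 only Cxcl14 was above background, and neither Lef1 nor Axin2 was.

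By limma 0 of 65956 clusters differed between genotypes in basal cells, with 8649 at an unadjusted p under 0.05 where chance gives 3298, and a lowest adjusted p of 0.129. The design's unmoderated test called 0 on log2 values (6357 at an unadjusted p under 0.05) and 0 on unlogged signals (6313), and the authors' deposited table holds 0 clusters with q under 0.05. With a term for sex, chosen after seeing the sex genes, the count stayed at 0 (7808 at an unadjusted p under 0.05) and the Notch list was no longer called (adjusted p = 0.212). Because 1 of 3 bitransgenic arrays per layer had the wild-type sex pattern, that term raised the standard error of the genotype comparisons by a factor of 1.225 at equal spread. Without the wild-type array X667_06_H the count was 87, 82 higher and 5 lower, and without the bitransgenic array X722_07_H it was 1, an unnamed cluster.

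In suprabasal cells no single gene passed the test of genotype either, and 7 lists were called. By median, the largest shifts were in immediate-early genes, at -0.59 with all 14 below 0, and in melanocyte genes, at -0.515, which were not called (adjusted p = 0.406). The melanocyte direction depended on 1 array. The median was 0.60 without X667_05_L, where the list was called upwards (adjusted p = 0.00307). It was -1.32 without X721_05_L, where the list was called downwards (adjusted p = 0.00749), and -0.14 without X682_11_L. Of 30 cell cycle genes 29 were above 0 in bitransgenic cells, with a median of 0.36, Cdk1 at 0.58, Top2a, the DNA topoisomerase of dividing cells, at 0.74 and Kif11, a spindle motor, at 0.85. Keratinocyte stress genes had a median of 0.31, with Krt16, a keratin of stressed epidermis, at 0.54, Areg, an EGF receptor ligand, at 0.81 and S100a9, an inflammatory calcium-binding protein, at 1.90 ± 1.253 (SE). The cell cycle, stress and immediate-early lists had 0 calls over all genes and 0 adjusted over the list alone. Camera gave adjusted p = 4.39e-07 for cell cycle, 0.00193 for stress and 0.000532 for immediate-early genes, against adjusted p = 0.583, 0.457 and 0.518 with an estimated correlation. The cell cycle shift depended on single arrays: its median was 0.06 without wild-type X721_08_L, where the list was not called (adjusted p = 0.13), 0.10 without bitransgenic X667_05_L, 0.67 without X721_05_L and 0.56 without X667_06_L. The stress median was 0.14 without X667_05_L, where the call was lost (adjusted p = 0.0808), 0.19 without X682_05_L and 0.63 without X721_05_L. The immediate-early median was -0.37 without X667_06_L, where the call was lost (adjusted p = 0.0626).

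Wnt components (median -0.10, 29 of 41 below 0, with Wnt7b at -0.34 and Wnt4 at -0.51) and Notch genes (median -0.12, 18 of 20 below 0, with Notch1 at -0.39 and Hes1, a Notch target, at -0.51) were lower in bitransgenic suprabasal cells, with 0 calls over all genes and 0 adjusted over the list alone (camera adjusted p = 0.0274 and 0.028, and adjusted p = 0.457 for both with an estimated correlation). Not above background in either group were 25 of the 41 Wnt, 14 of the 20 Notch and 10 of the 20 stress genes, and 5 of the 30 cell cycle genes. At the bounds the medians were 0 for the first 3 lists, largely set by their dim genes, and 0.175 for cell cycle genes. Over the genes above background in both groups the medians were -0.13 for 15 Wnt and -0.21 for 5 Notch genes. They were 0.54 for 8 stress and 0.34 for 16 cell cycle genes. No Merkel cell or immune gene was above background. Merkel cell genes had a median of -0.18, with Atoh1 (-0.39) called adjusted over the list alone and 0 over all genes, and immune genes one of -0.08 with 0 calls on either basis (camera adjusted p = 0.000532 and 0.0112, and adjusted p = 0.457 and 0.518 with an estimated correlation). The Wnt and Notch calls were lost without X667_06_L (adjusted p = 0.163 and 0.0846), X721_05_L (0.0565 and 0.0513) or X667_05_L (0.0955 for both), and the immune call without X682_11_L (0.0998), X721_05_L (0.0565) or X667_05_L (0.0808). The Wnt median was -0.07 without X667_06_L. Cyclic loess also lost the immune call (adjusted p = 0.0784). Both scalings added hair follicle genes (adjusted p = 0.0151 centred and 0.00547 with loess) and Wnt targets (0.0447 and 0.0372), centring added melanocyte genes (0.0492), and loess added basal keratinocyte (0.00547), early differentiation (0.0101) and spindle orientation genes (0.00117), all downwards on 12 arrays. Each of these added calls was lost without 1 or more arrays. Centred, these were 3 arrays for hair follicle genes, 3 for Wnt targets and 7 for melanocyte genes. Centred melanocyte genes were called upwards without X667_05_L (adjusted p = 0.00778, median 0.64). With loess they were 2 for hair follicle genes, 3 for Wnt targets, 2 for basal keratinocyte and 1 each for early differentiation and spindle orientation genes. Among further genes, Sun1 (-0.34), Lef1 (-0.45), Axin2 (-0.12), Lmnb1 (0.08), Lmnb2 (0.00), Sun2 (-0.15), Krt5 (-0.28), Krt14 (-0.12), Itga6 (0.02), Trp63 (-0.11), Krt1 (0.00), Krt10 (-0.09), Lor (-0.16), Flg (0.04), Mki67 (0.24) and Cdkn1a (-0.02) were not called. The genes with the smallest p, as values only, were Pbdc1 (0.41), the cohesin gene Smc3 (0.33), Selenok-ps1 (0.29), Chmp2b (0.29) and Med6 (0.38), and Trav15n-2 (-0.37), Atoh1, Pabpc1l2a-ps (-0.31), Cacna2d2 (-0.24) and Cby3 (-0.30). Of these 10, 7 were not above background in either group.

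By limma 0 of 65956 clusters differed between genotypes in suprabasal cells, with 3440 at an unadjusted p under 0.05 where chance gives 3298, and a lowest adjusted p of 0.866. The design's unmoderated test called 0 on log2 values (4558 at an unadjusted p under 0.05) and 0 on unlogged signals (4499), and the authors' deposited table holds 0 clusters with q under 0.05. With the term for sex all 7 list calls of this comparison were lost, with adjusted p = 0.122 for cell cycle and Wnt components, 0.205 for Notch, 0.818 for stress, 0.0827 for immediate-early genes and 0.0662 for immune and Merkel genes. The first number of the code pairs the 3 arrays of each genotype in this layer, and with these pairs as a block, added after seeing the data, 0 clusters were called (5479 at an unadjusted p under 0.05). All 7 lists were still called, nuclear envelope genes were added (adjusted p = 0.0358, and adjusted p = 0.57 with an estimated correlation), and 0 of 24 lists were called with an estimated correlation. The mean difference of cell cycle genes was 0.476, 0.162 and 0.459 in the pairs of X667_05_L, X682_05_L and X721_05_L with their wild-type partners.

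**Figure D4:**
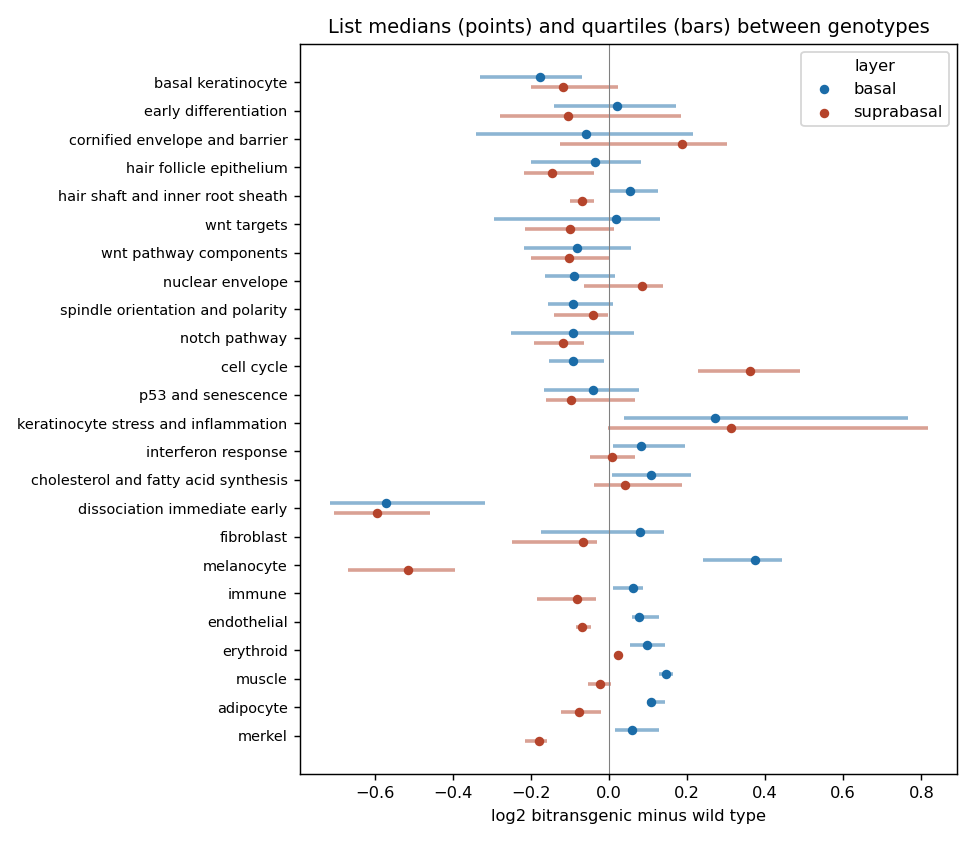
Median (points) and quartiles (bars) of the bitransgenic minus wild-type log2 difference over the members of each list (horizontal axis), for basal and suprabasal cells. Immediate-early genes have medians of -0.57 and -0.59, and cell cycle genes -0.09 in basal and 0.36 in suprabasal cells.

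Whether the genotype difference itself depends on the layer was tested as an interaction, basal minus suprabasal. Lmna had an interaction of -0.12 ± 0.138 (SE), Lmnb1 of -0.32 and Mki67 of -0.61 ± 0.275 (limma's adjusted p = 0.486). By limma 0 clusters were called, with 6734 at an unadjusted p under 0.05 and a lowest adjusted p of 0.393; the design's test was not run for this contrast. Camera called 7 lists, 5 upwards and 2 downwards, which the closing part gives one by one with their values under an estimated correlation. Centring the arrays shifted the median of all genes by -0.103 in this contrast.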

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

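The tests of the bitransgenic array X667_05_L, of background, of the size of the layer effect and of the share of keratinocytes, the fit with a term for sex the list tests under other scaling and the regroupings that keep pairs, were chosen only after the result was seen. Of the gene lists, 7 differed between layers in their genotype effect by the test of the difference itself, the interaction in camera. Cell cycle genes had a median interaction of -0.42 (bitransgenic minus wild type, basal minus suprabasal; adjusted p = 1.448e-07, and adjusted p = 0.785 with an estimated correlation) and 29 of 30 were below 0. Nuclear envelope genes had -0.12 (0.001842, and adjusted p = 0.351 with an estimated correlation), with 19 of 26 below 0. Merkel cell genes had 0.29 (0.0123, and adjusted p = 0.602 with an estimated correlation), with Sox2, Atoh1 and Isl1 called adjusted over the list alone. Immune genes had 0.19 (0.01337, and adjusted p = 0.688 with an estimated correlation), endothelial genes 0.12 and adipocyte genes 0.17 (0.01337, and adjusted p = 0.55 with an estimated correlation for both), and muscle genes 0.16 (0.01371, and adjusted p = 0.61 with an estimated correlation). No gene of the 7 lists was called over all genes, and no gene of the Merkel, immune, endothelial, adipocyte and muscle lists was above background in any group. Without 1 array the cell cycle median was -0.13 (X721_08_L), -0.19 (X667_05_L) or -0.69 (X721_05_L), the nuclear envelope median -0.20 (X667_06_H) and the immune median 0.13 (X721_05_L), and the calls of immune genes (adjusted p = 0.0662 without X682_11_L and 0.0555 without X667_05_L) and muscle genes (0.0915 without X682_11_L) were lost. With arrays centred, the cell cycle, nuclear envelope and Merkel lists were still called, and with cyclic loess the cell cycle and Merkel lists, while loess added early differentiation genes upwards (adjusted p = 0.0321), a call lost without any of 5 arrays. Regrouping the arrays cannot exclude chance. Of 100 regroupings, the real one included, 49 gave at least 7 lists and the highest other gave 14. For clusters the real count of 0 is reached by any regrouping, so this tests nothing. These regroupings did not keep the pairs of codes or the layers, so the layer difference could enter their contrast. Of 100 regroupings that kept the pairs, the real one included, 59 gave at least 7 lists. Most of these turned the layers of some arrays, so the layer difference could enter them too, and neither 49 nor 59 measures chance alone. In 3 that gave more than 5 clusters, the highest 1674, the contrast was the layer difference itself. The 10 that kept pairs and layers are too few for a share under 0.05, and 4 of them, the real one included, gave at least 7 lists, with 0 clusters and 8 lists as the highest others.

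The first pattern is 957 clusters called between layers in wild type and 0 in bitransgenic cells, though the interaction called 0 clusters and the effects are not shown to differ. The layers share 3 codes in wild type but only 2 in bitransgenic cells, where X722_07_H and X682_05_L have no partner. The bitransgenic comparison therefore sets partly different codes against each other, and what this changes was not tested. The suprabasal array X667_05_L may pull its group towards basal: without it 126 clusters were called, more than the 0 that would have argued against this and fewer than the wild-type count divided by 1.5 that would have spoken for it. A smaller layer effect in bitransgenic animals, the genotype term of the design, stays open too, because the median over 3 lists of the wild-type minus the bitransgenic effect was -0.117, within its SD of 0.428 over the lists. That median met the bound written for a layer effect at least as large in bitransgenic cells, but with a spread wider than itself it decides nothing. Over the 957 clusters the median ratio of the bitransgenic to the wild-type difference was 0.24. Those clusters were chosen on the wild-type difference, so this ratio cannot decide it either. The 10 splits of 6 arrays are too few for a share under 0.05: wild type gave 957 clusters and 14 lists, the highest other splits 1 and 9, and among the 4 splits that part all pairs of codes the highest others gave 0 clusters and 7 lists; bitransgenic cells gave 0 and 7, with 0 and 8 as the highest others among all 10 and among the 4.

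The second pattern is the higher signal of pigment-cell genes in suprabasal arrays. A lower share of keratinocytes alone would raise every other cell type alike. The lowest median of the fibroblast, immune, endothelial, muscle and adipocyte lists was -0.2, which met the bound written against this, but that bound was wrong because 42 of their 45 genes were not above background in either group. Of the other 3, all fibroblast genes, 2 were above background in both groups with a median of 0.57, higher in basal cells, and 1 in 1 group only. These are too few to decide, so this stays open. Melanocytes sorted with suprabasal cells remain a candidate source, and in 5 pigment genes outside the list (Trpm1 -1.48, Oca2 -1.32, Tspan10 -1.30, Gpr143 -1.06 and Rab38 -0.11) the median was -1.3, between the bounds of -2 and -1 set beforehand, and 4 of the 5 were not above background in either group, so the test left it open. The labels name a sort of cells but no step that would remove melanocytes, and no biological explanation by group was tested.

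The third pattern is 0 clusters between genotypes in either layer. Unequal shares of female animals stay open: a term for sex left the count at 0 in both layers, which met the bound written against this explanation, but that bound was wrong because the term raised the standard error of these comparisons by a factor of 1.225 and low power is itself open. Too few arrays could not be told apart from small effects: 88% of simulated log2 changes of 1 were recovered, which met the bound written against this explanation, but that bound was wrong. Simulated noise is independent between genes, and the planted log2 changes of 2 and 4 eased the adjusted threshold for the smaller ones. Between real bitransgenic layers 7 melanocyte genes that differed at least 2-fold as measured, 4 at the bounds, had 0 calls. The genotype effect itself remains open as untested beyond these arrays. The 10 splits per layer are too few for a share under 0.05: the real basal split gave 0 clusters and 8 lists and the highest others 1 and 9, and the suprabasal split 0 and 7 against 0 and 12, or 0 and 11 among the 4 splits that part all 3 pairs by first number.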

How the results depend on the processing

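The test on unlogged signals, the term for sex, leaving out chromosomes X and Y, list tests blocked by the first number of the code and the block of suprabasal pairs were chosen only after the result was seen. The count of 957 between wild-type layers was 342 with centring, 262 with cyclic loess, 476 with trend and robust moderation, 1860 with array weights, 3600 with the code as a random block, 4 with only the 2 groups compared (Aadac, Dct, Fads2 and an unnamed cluster, chosen after their values were seen), and 0 with the design's test on log2 values or unlogged signals (11918 and 11869 at an unadjusted p under 0.05). Fits restricted to clusters above the median of cluster means gave 1521, and fits restricted to clusters with 1 symbol gave 1488. The cause of these changes was not tested. The count alone stayed within 1.5 times at 758 with the first number of the code as a block (364 higher, 394 lower, 478 of them among the 957), 1312 with pairs as a fixed block (351 shared), 779 with sex (666 shared) and 932 without X and Y (923 shared). Of the 43 list calls, 0 held with an estimated correlation, 11 with directional fry, 34 with sex, 42 with the random block and 36 with the first number as a block, where the basal genotype cell cycle list turned upwards and was not called (adjusted p = 0.826). Directional fry called 9 lists between wild-type layers and 2 in the interaction. It called 0 in either genotype comparison and 0 between bitransgenic layers. The first number did not pair the basal genotypes (correlations of 0.229 and -0.157). Leaving out 1 array gave 0 to 2903 clusters between wild-type layers, 0 to 87 between basal genotypes, 0 to 0 between suprabasal genotypes, 0 to 126 between bitransgenic layers, 0 to 0 in the interaction and 37 to 50 list calls. No called named gene changed sign under the alternatives run on single genes, which leave out the test on unlogged signals, but the larger share of wild-type layer calls turned from lower (28% higher) to higher with centring (66.4%), without X682_11_H (66.7%) and without X682_05_L (55.6%). Of 34 called named genes, 20 were still called with centring, 16 with loess, 22 with trend and robust moderation, 28 with sex, 34 with the random block, 31 with fixed pairs, 27 with the first number as a block, 1 with only the 2 groups compared and 0 with the design's test. Without 1 array 0 of the 34 were called for 6 arrays (X682_11_H, X721_08_H, X721_05_H, X682_11_L, X721_08_L and X682_05_L), 2 without X722_07_H and 18 to 34 without the others. Apart from the changes given with the comparisons, blocking by the full code, or by first number in suprabasal pairs, changed no other call of a list tested or gene named. Clusters near background can hide changes: at most 12.3% on an array lay above the 95th percentile of intronic controls.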

Other observations

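The tests of annotated terms between genotypes were chosen only after the result was seen. They were not repeated with a term for sex, other scaling or an array left out. The list calls of the suprabasal genotype comparison were lost with the term for sex. In suprabasal cells, genes of ribosome biogenesis were higher in bitransgenic arrays, with a median of 0.193 over 76 genes (camera adjusted p = 2.01e-14, and adjusted p = 0.633 with an estimated correlation), as were genes of ribosomal RNA processing, with 0.197 over 96 genes (adjusted p = 5.86e-14, and adjusted p = 0.633 with an estimated correlation). In basal cells, genes of chromatin modification were lower by a median of -0.073 over 241 genes (adjusted p = 1.62e-07, and adjusted p = 0.425 with an estimated correlation) and genes of telomere maintenance by -0.107 over 28 genes (adjusted p = 2.41e-05, and adjusted p = 0.425 with an estimated correlation). Of 1718 terms, 178 were called in basal cells (8 up, 170 down) and 175 in suprabasal cells (79 up, 96 down), and 0 in either with an estimated correlation. The basal terms named do not stand apart from this general downward shift. Protein ubiquitination, DNA repair and mitosis were also lower there, with a smaller p than telomere maintenance (camera adjusted p = 1.1e-05 each). In both layers 2 of 3 bitransgenic arrays had Xist above the Y-linked genes.

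S100a8 and S100a9, calcium-binding proteins of inflamed epidermis, followed the codes rather than the layers. S100a8 was 9.82 and 9.79 on the basal and suprabasal wild-type arrays X682_11_H and X682_11_L, 10.74 and 11.02 on bitransgenic X667_05_H and X667_05_L, 10.23 on X722_07_H and 10.69 on X682_05_L. It was 4.01 and 4.48 on wild-type X667_06_H and X667_06_L, 3.99 and 4.29 on X721_08_H and X721_08_L, and 5.40 and 6.39 on bitransgenic X721_05_H and X721_05_L. Fos, an immediate-early gene, was 11.94 and 11.54 on wild-type basal X667_06_H and X721_08_H and 9.94 on X682_11_H. Fos differed within a code, at 10.78 on X721_08_L, so these values do not show that it followed the codes. X722_07_H and X682_05_L have no other array with their code. Among bitransgenic arrays S100a8 was high where Xist was high and lower on X721_05_H and X721_05_L, so code and sex pattern cannot be told apart there. Wild-type X682_11_H and X682_11_L had high S100a8 with low Xist. Why S100a8 and S100a9 differed between codes was not tested.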
